A study of Mus musculus with 30 samples.

How the data were processed

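Microglia from mice were profiled by droplet single-cell RNA sequencing in 8 libraries. Per the titles in the labels, these are WT_Con (2 libraries), APP_Con (2), APP_IL33 (2), Veh_IL33 (1) and DB2313_IL33 (1). APP/PS1 mice carry mutant transgenes of amyloid precursor protein and presenilin 1 and are a model of Alzheimer's disease. IL-33 is a cytokine of the IL-1 family, and DB2313 is a small-molecule inhibitor of the transcription factor PU.1, which Spi1 encodes. The labels give no dose, age or duration. ATAC-seq, PU.1 and H3K4me3 samples of the series were not analysed here.

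Per the labels' protocols, libraries were made with the Chromium Single Cell 3′ v2 kit and sequenced on a NextSeq 500. The deposited matrices hold UMI counts, not normalized, for 27998 genes and 737280 barcodes per library. Per the file headers, they were written by Cell Ranger 3.0.1 for the WT_Con, APP_Con and APP_IL33 libraries and by 3.0.2 for Veh_IL33 and DB2313_IL33. The submitters' processing notes name mm10 as the genome build, and they name Cell Ranger, BWA, Picard, HOMER, deepTools and bedtools without saying which step each served. The matrices are unfiltered, so cells had to be called. Counts at the 3′ end do not tell apart reads of near-identical paralogs, which concerns H2-Q6 and other MHC class I genes. Total counts per library ran from 8407503 UMIs in DB2313_IL33 to 55568069 in APP_IL33 replicate 2.

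A barcode was called a cell when its UMI total reached the 99th percentile of the 3000 highest totals of its library divided by 10, and at least 500. Cells with under 300 genes or over 10% mitochondrial UMIs were removed. Scrublet, as run in scanpy, marked 11 cells (0.0606%) as doublets, so its automatic threshold did not work; those cells were removed and other doublets remain. An alternative chosen after seeing this removed the 361 cells with the highest doublet scores. This left 18154 cells. They were scaled to 10000 counts, log-transformed and clustered (scanpy 1.11.5, leidenalg 0.10.2, 2000 variable genes, 30 principal components, 15 neighbours, resolution 1). Mitochondrial, ribosomal-protein, sex-linked and MHC class II genes were kept out of the variable genes.

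Clusters were named from markers fixed before the data were examined, by a scoring rule set after the clusters were seen. A cluster took the name of a cell type with at least 3 of its markers, and none of another type's, among the 10 genes of largest fold. A cluster with no marker of another type there was called microglia-like when microglial markers were detected in at least 70% of its cells on average. Of the 19 clusters, 13 were microglia-like and held 15978 cells. Others were border-associated macrophage-like, neutrophil-like and oligodendrocyte-like, and 3 stayed unnamed. Unnamed cells made up 3.57% and 3.13% of the WT_Con libraries, 1.50% and 4.86% of APP_Con, 2.14% and 2.78% of APP_IL33, 6.72% of Veh_IL33 and 18.6% of DB2313_IL33. Cluster sizes were not compared between groups. Most microglia-like cells of WT_Con replicate 1 lay in cluster 0 and of replicate 2 in cluster 1, most APP_Con and APP_IL33 cells in clusters 3, 6, 9 and 10, and most Veh_IL33 and DB2313_IL33 cells in cluster 7, so comparisons of the class also compare these clusters.

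Raw counts were summed per library over microglia-like cells. Sums ran from 4571301 UMIs (DB2313_IL33) to 38683420 (APP_IL33 replicate 2). The 6 libraries of WT_Con, APP_Con and APP_IL33 were fitted together with edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood F test, group as the only term). This left 12355 genes, 3 residual degrees of freedom and a common biological coefficient of variation of 0.210. P-values were adjusted by the Benjamini-Hochberg method and genes passed at an adjusted p under 0.05. Errors of log2 fold changes are the absolute change divided by the square root of F. No label says that replicates come from separate animals, so p-values measure the spread between these libraries, which may be technical in part. Replicate libraries differed by far more than counting noise (chi-square per degree of freedom of 70.0 in WT_Con, 54.0 in APP_Con and 71.3 in APP_IL33).

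For MHC class II, each microglia-like cell was thinned to 1000 UMIs. It was positive with 3 or more UMIs summed over H2-Aa, H2-Ab1, H2-Eb1 and Cd74 and negative with 0; cells in between belonged to neither class. Every microglia-like cell had 1000 UMIs or more. Shares carry 95% Wilson intervals, which cover counting error only. Positive and negative cells of both APP_IL33 libraries and Veh_IL33 were summed apart and compared in edgeR with the library as a block, without the 4 defining genes (10760 genes, 2 residual degrees of freedom, coefficient of variation 0.0581). DB2313_IL33 and Veh_IL33 were compared as log2 ratios of CPM after adding 1 count, with no test, because each group has 1 library. List medians were set among 10000 random lists matched on mean CPM.

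Gene lists were fixed before the data were examined. They were homeostatic microglia, disease-associated microglia, MHC class II, MHC class I, interferon response, chemokines and cytokines, alternative activation, IL-33 receptor and NF-kappaB, phagocytic receptors, lysosome, complement, microglial transcription factors, immediate early and dissociation genes, cell cycle, cholesterol and lipid handling, glycolysis, nuclear-encoded oxidative phosphorylation, Alzheimer risk genes, TGF-beta pathway, mitochondrial genome, ribosomal proteins and sex-linked genes, with marker lists of 16 other cell types. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated correlation and with fry.

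Named genes followed a rule fixed before the data were examined. It took, among genes past the test at a mean of at least 20 CPM whose groups did not overlap (or, in the paired comparison, that moved the same way in every library), the 10 largest changes each way. It left out sex-linked, mitochondrial, ribosomal-protein and predicted genes. It added up to 4 members of each list, of which some are named in the text, and 12 genes always named: Spi1, Il1rl1, Il1rap, Cd74, H2-Ab1, H2-Aa, Apoe, Trem2, Cst7, P2ry12, Tmem119 and Cx3cr1. For DB2313_IL33 against Veh_IL33 it took the 10 largest ratios each way among genes at 50 CPM or more in either library. Some genes that the rule takes are not reported here. Genes named outside the rule are said to have been chosen after their values were seen. Gene positions come from RefSeq on GRCm38, the assembly of mm10, which placed 11959 of the 12355 tested genes.

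The alternatives tried were DESeq2 1.42.0, upper-quartile scaling, no low-count filter, fits of only the 4 libraries compared, the replicate number as a block, thinned library sums, another cell rule (at least 1000 UMIs), a mitochondrial limit of 5%, kept doublets, all cells, other limits and depths for MHC class II, and each library left out. Removing cells by doublet score or over 25000 UMIs, and the replicate block on the other cell rule, were added after the data were seen. So were fits that gave 1 library of a shared control group to each of 2 comparisons (2 residual degrees of freedom). Scripts were tested on simulated counts with 200 changed genes. For APP_IL33 against APP_Con (12188 genes), the test recovered 29.9% of genes simulated at a log2 change of 1, 83.1% at 2 and 93.8% at 3, and 13 of the 148 calls were unchanged genes. For positive against negative cells (10639 genes) it recovered 66.7% at 0.5, 89.4% at 1 and 100% at 2, and 13 of the 181 calls were unchanged.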

Results

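The series asks how IL-33 changes microglia in APP/PS1 mice and what part the transcription factor PU.1 has in it. The single-cell libraries were 2 of WT control mice (WT_Con), 2 of APP/PS1 control mice (APP_Con), whose handling the labels do not give, 2 of APP/PS1 mice given IL-33 (APP_IL33), and 1 each of IL-33 with vehicle (Veh_IL33) and IL-33 with the PU.1 inhibitor DB2313 (DB2313_IL33). Library totals were 31105170 and 45451019 UMIs in WT_Con, 28640893 and 48226045 in APP_Con, 35030324 and 55568069 in APP_IL33, 21631814 in Veh_IL33 and 8407503 in DB2313_IL33. Microglia-like cells numbered 1858 and 2177 in WT_Con, 1573 and 2469 in APP_Con, 2444 and 2912 in APP_IL33, 1798 in Veh_IL33 and 747 in DB2313_IL33. Their median depth was 8349 and 8489 UMIs, 10662 and 9177, 8035 and 9222, 6127 and 4172 in the same order.

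The genotype labels of Veh_IL33 and DB2313_IL33 say WT. Over 397 genes changed between APP_Con and WT_Con, on a scale from 0 at WT_Con to 1 at APP_Con, the median position was 1.07 in Veh_IL33 and 1.08 in DB2313_IL33. It was 0.891 and 0.900 in the APP_IL33 libraries. Prnp, the prion protein gene, chosen after its values were seen, stood at 2.30 and 1.40 CPM in WT_Con, 15.5 and 16.5 in APP_Con, 11.1 and 17.7 in APP_IL33, 14.8 in Veh_IL33 and 16.8 in DB2313_IL33. Veh_IL33 and DB2313_IL33 were also the libraries of male mice (Ddx3y at 202 and 180 CPM, Xist at 0), while the other 6 held Xist and no Ddx3y. These libraries are therefore called by their treatment, and no comparison here rests on their genotype label.

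APP_Con was compared with WT_Con for the effect of the APP/PS1 genotype. In microglia-like cells of APP/PS1 mice, 17 of 26 disease-associated genes and 10 of 22 lipid-handling genes rose (adjusted p = 0.0758 and 0.192 for these lists with an estimated correlation). Apoe, a lipid carrier, rose from 612 ± 143 to 9109 ± 1404 CPM (SD, n = 2 libraries each; log2 fold change 4.08 ± 0.23 SE, edgeR quasi-likelihood adjusted p = 0.0028). Cst7, an inhibitor of cathepsins, rose from 23.8 ± 10.3 to 1630 ± 185 CPM (6.28 ± 0.44, adjusted p = 0.00366). Spp1, which encodes osteopontin, rose from 51.0 ± 4.98 to 293 ± 33.9 CPM (2.70 ± 0.20). The chemokine gene Ccl2 fell from 534 ± 64.5 to 125 ± 3.13 CPM (log2 fold change -1.92 ± 0.21, adjusted p = 0.00898).

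In all, 406 of 12355 genes changed, 346 higher and 60 lower. The 10 largest rises at 20 CPM or more were in Baiap2l2 (8.74), Gpnmb (7.76), the growth factor gene Igf1 (6.39), Cst7, the fatty-acid binding protein gene Fabp5 (5.54), Nrp1 (4.73), Apoe, Cox6a2 (3.98), the integrin gene Itgax (3.94) and the lipoprotein lipase gene Lpl (3.71). Among the largest falls were Zfp69 (-2.82), Ccl2, Cap1 (-1.75), Gp9 (-1.64), Klhdc8b (-1.52), the transcription factor genes Ets1 (-1.40) and Klf2 (-1.40), and Bank1 (-1.28). Adjusted p of these 18 genes ran from 0.0028 to 0.0351. Zfp69 and Cap1, both on chromosome 4 of GRCm38 (starts 120930133 and 122859048), were low in APP_Con (7.38 and 5.08 CPM for Zfp69) and in DB2313_IL33 (5.03) but not in APP_IL33 (30.1 and 32.1). Homeostatic genes did not pass singly: P2ry12 had -0.46 ± 0.14 (adjusted p = 0.139), Tmem119 -0.71 ± 0.17 (0.0890) and Cx3cr1 -0.07 ± 0.15 (0.858). Other genes always named were not past the test either: Trem2 0.81 ± 0.20 (0.0956), Spi1 -0.31 ± 0.18 (0.415), Il1rl1 -0.25 ± 0.33, Il1rap 0.00 ± 0.30, H2-Aa 1.54 ± 0.90, H2-Ab1 1.00 ± 0.81 and Cd74 0.80 ± 0.69. DESeq2 called 1150 genes and the fit without a low-count filter 813. With the replicate number as a block 1253 passed, though no label says what that number marks. The count was 103 without WT_Con replicate 1, 166 without WT_Con replicate 2, 186 without APP_Con replicate 1, 165 without APP_Con replicate 2, and 179 and 176 without APP_IL33 replicate 1 or 2, 188 over all cells and 195 in a fit of these 4 libraries only.

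**Figure D1:**
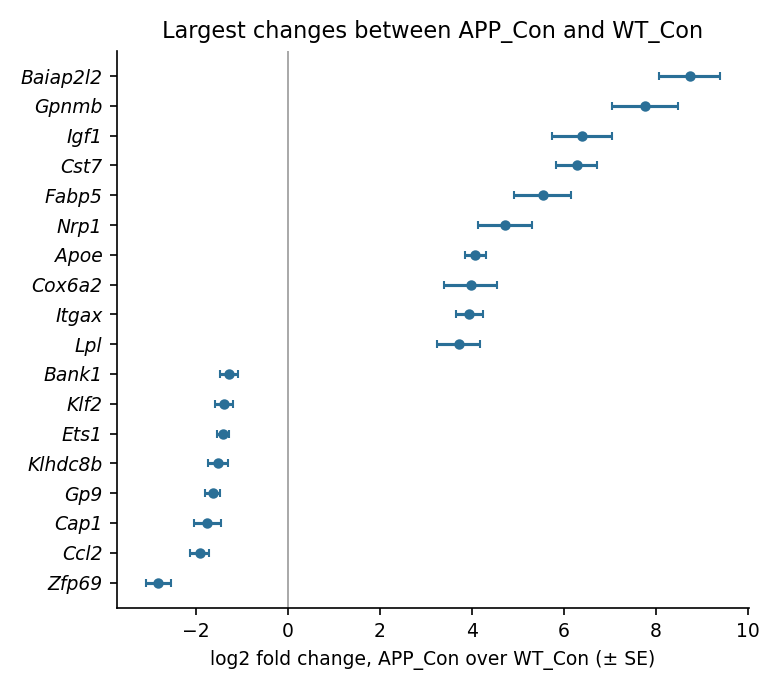
Log2 fold change of the 18 named genes of largest change between APP_Con and WT_Con (x axis; points, edgeR estimate; bars, ± SE; n = 2 libraries each). Rises reach 8.74 in Baiap2l2 and falls reach -2.82 in Zfp69.

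Genes were grouped by the fixed lists. Of the disease-associated microglia list, 17 of 26 members rose and 0 fell (25 rose when adjusted over the list alone). Examples are Apoe, Cst7, Itgax and the receptor tyrosine kinase gene Axl (3.32 ± 0.45). The list passed camera with a preset correlation (adjusted p = 1.21e-50) and fry (adjusted p = 0.00882), but not camera with an estimated correlation (adjusted p = 0.0758). Of cholesterol and lipid handling genes, 10 of 22 rose (17 adjusted over the list alone), among them the sterol synthesis gene Sqle (4.16 ± 0.36) and Ch25h (3.41 ± 0.28), which makes 25-hydroxycholesterol; adjusted p = 0.192 with an estimated correlation. Of nuclear-encoded oxidative phosphorylation genes, 9 of 34 rose (30 adjusted over the list alone), such as Ndufa1 (1.49 ± 0.19), Ndufv3 (0.91 ± 0.14) and Cox5b (0.81 ± 0.14); adjusted p = 0.312 with an estimated correlation. Interferon response genes rose in 4 of 24 cases (16 rose and 1 fell adjusted over the list alone), with Ifi27l2a at 3.43 ± 0.39, Ifitm3 at 2.57 ± 0.36 and Bst2 at 1.31 ± 0.22; adjusted p = 0.345 with an estimated correlation. Among phagocytic receptors 5 of 22 rose (7 rose and 1 fell adjusted over the list alone), including Axl and the signalling adaptor gene Tyrobp (1.18 ± 0.21); adjusted p = 0.192 with an estimated correlation. Among lysosome genes 7 of 31 rose (14 rose and 2 fell adjusted over the list alone), including the cathepsin gene Ctsb (1.16 ± 0.14), Cd63 (1.75 ± 0.21) and Cd68 (0.94 ± 0.13); adjusted p = 0.192 with an estimated correlation. In glycolysis 2 of 15 rose (9 adjusted over the list alone), Tpi1 (1.30 ± 0.19) and Pgam1 (0.76 ± 0.13); adjusted p = 0.246 with an estimated correlation. Of ribosomal proteins 2 of 36 rose, Rps20 (0.80 ± 0.13) and Rpl23 (0.97 ± 0.17) (31 adjusted over the list alone); adjusted p = 0.401 with an estimated correlation.

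The immediate early and dissociation list went the other way: 2 of 25 fell (7 adjusted over the list alone), Klf2 and Jun (-0.89 ± 0.17), and adjusted p = 0.246 with an estimated correlation. All 25 members stood lower in APP_Con, with a median of -0.66. Of the 1858 microglia-like cells of WT_Con replicate 1, 1536 lay in cluster 0. Hspa1a, Hsp90aa1 and Hspa1b of this list were among the 10 leading genes of that cluster. Whether dissociation or genotype set these falls, that of Klf2 included, was not tested. The homeostatic list passed downward with 0 of 17 members past the test (0 adjusted over the list alone; adjusted p = 0.246 with an estimated correlation). The IL-33 receptor and NF-kappaB list also passed downward, with 0 of 20 past the test and 1 lower when adjusted over the list alone (adjusted p = 0.674 with an estimated correlation and 0.452 with fry). Its adjusted p was 0.266 without WT_Con replicate 1 and 0.440 without APP_Con replicate 2. Markers of other cells moved too. Monocyte and endothelial cell lists passed upward with 1 of 6 members risen in each, Fn1 (2.00 ± 0.28) and Flt1 (4.69 ± 0.38). Adjusted over the list alone the counts were 3 and 1, and camera with an estimated correlation gave adjusted p = 0.246 and 0.280. With the replicate number as a block, the endothelial list no longer passed camera with the preset correlation. The endothelial list had adjusted p = 0.0642 without APP_Con replicate 2 and 0.0730 over all cells, and the monocyte list 0.560 over all cells. Fn1 had 0.139 and 0.109 without WT_Con replicate 1 or 2, 0.0744 without APP_Con replicate 1 and 0.0852 over all cells. Of 32 lists tested, 13 passed with the preset correlation, 0 with an estimated one and 13 with fry. These were not all the same lists: interferon response (adjusted p = 0.0573) and the IL-33 receptor and NF-kappaB list did not pass fry, while alternative activation (0.0204, pointing down) and the mitochondrial genome (0.0409, pointing up) passed only fry. Lists not past camera with a preset correlation held a few single changes. Chemokines and cytokines had 2 rises, Cxcl1 (2.87 ± 0.37) and Ccl6 (1.81 ± 0.29), and 1 fall, Ccl2. Microglial transcription factors had 2 rises, Hif1a (1.46 ± 0.19) and Bhlhe40 (2.91 ± 0.44). Alzheimer risk genes had 1 rise, Apoe, and 1 fall, Ms4a6b (-0.95 ± 0.12). Among markers of other cells, named after their values were seen, 4 rose, Dab2 of border-associated macrophages (1.43 ± 0.21), Klrb1c of T or NK lymphocytes, Cspg4 of oligodendrocyte precursors and Folr1 of choroid plexus, the last 3 at under 5 CPM in each of these libraries, and 2 fell, Cd79b of B lymphocytes (-1.11 ± 0.19) and Mag of oligodendrocytes (-0.75 ± 0.14). None of these 6 passed without either library of WT_Con or of APP_IL33, over all cells or in a fit of these 4 libraries only, and Dab2 turned to -0.22 over all cells. Without APP_Con replicate 1 only Dab2 passed, and without replicate 2 only Cspg4. MHC class II, MHC class I, alternative activation, complement, cell cycle, TGF-beta pathway and mitochondrial genome lists had 0 genes past the test each. The MHC class II median was 0.53 while camera pointed down (adjusted p = 0.919).

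APP_IL33 was compared with APP_Con for the effect of IL-33. The means of MHC class II genes stood higher in APP_IL33, but the 2 libraries of each group lay so far apart that none passed. H2-Aa, an MHC class II chain, stood at 523 ± 535 against 111 ± 84.7 CPM (SD, n = 2 each; log2 fold change 2.21 ± 0.91), H2-Ab1 at 397 ± 351 against 90.8 ± 76.0 (2.11 ± 0.83), H2-Eb1 at 307 ± 286 against 61.1 ± 42.0 (2.31 ± 0.83) and the invariant chain gene Cd74 at 1242 ± 1154 against 475 ± 271 (1.37 ± 0.70). Without APP_IL33 replicate 1, Cd74 turned to -0.0502, and H2-Aa stood at 0.48, H2-Ab1 at 0.82 and H2-Eb1 at 0.89. That fit sets APP_IL33 replicate 2 against both APP_Con libraries. In replicates 1 and 2, Cd74 stood at 2058 and 426 CPM in APP_IL33 and at 667 and 284 in APP_Con. H2-Aa stood at 901 and 145 against 171 and 51.6, and H2-Ab1 and H2-Eb1 were also higher at each number. The labels do not say whether a number pairs libraries. The 6 genes that changed were others: Gnb4 rose, and Syn2, Rnf150, Clgn, Scoc and Arsb fell. Values of Apoe (-0.46 ± 0.21), Fabp5 (-0.63 ± 0.50), Cst7 (-0.32 ± 0.35) and H2-D1 (-0.64 ± 0.17) did not pass.

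Scoc, a Golgi protein gene, stood at 17.5 ± 4.49 against 228 ± 59.5 CPM (log2 fold change -3.66 ± 0.30, adjusted p = 0.0354), and Arsb, which encodes the lysosomal enzyme arylsulfatase B, at 147 ± 2.27 against 566 ± 15.9 (-1.92 ± 0.15, adjusted p = 0.0336). The remaining 4 lay under 20 CPM on average and were named after their values were seen. Gnb4, a G protein subunit gene, had 616 UMIs in APP_IL33 and 2 in APP_Con, a ratio of 255 with a counting interval of 70.4 to 2114. Syn2, a synapsin gene, had 5 against 441 UMIs (adjusted p = 0.0173), Rnf150 had 10 against 401 (0.0336) and Clgn, a chaperone gene, 16 against 765 (0.0392). On GRCm38, Rnf150 (ENSMUSG00000047747, 82863266 to 83091271), Clgn (ENSMUSG00000002190, 83389790 to 83428552) and Scoc (ENSMUSG00000063253, 83434492 to 83458436) are neighbours on chromosome 8. Arsb (ENSMUSG00000042082) starts at 93771679 on chromosome 13, Gnb4 (ENSMUSG00000027669) at 32578587 on chromosome 3 and Syn2 (ENSMUSG00000009394) at 115134902 on chromosome 6. Of the 12 values of these 6 genes in Veh_IL33 and DB2313_IL33, 11 lay nearer to APP_Con than to APP_IL33 on a log2 scale (CPM + 0.1), the exception being Arsb in DB2313_IL33. In CPM 9 did, and Arsb in both libraries and Clgn in DB2313_IL33 lay nearer to APP_IL33.

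**Figure D2:**
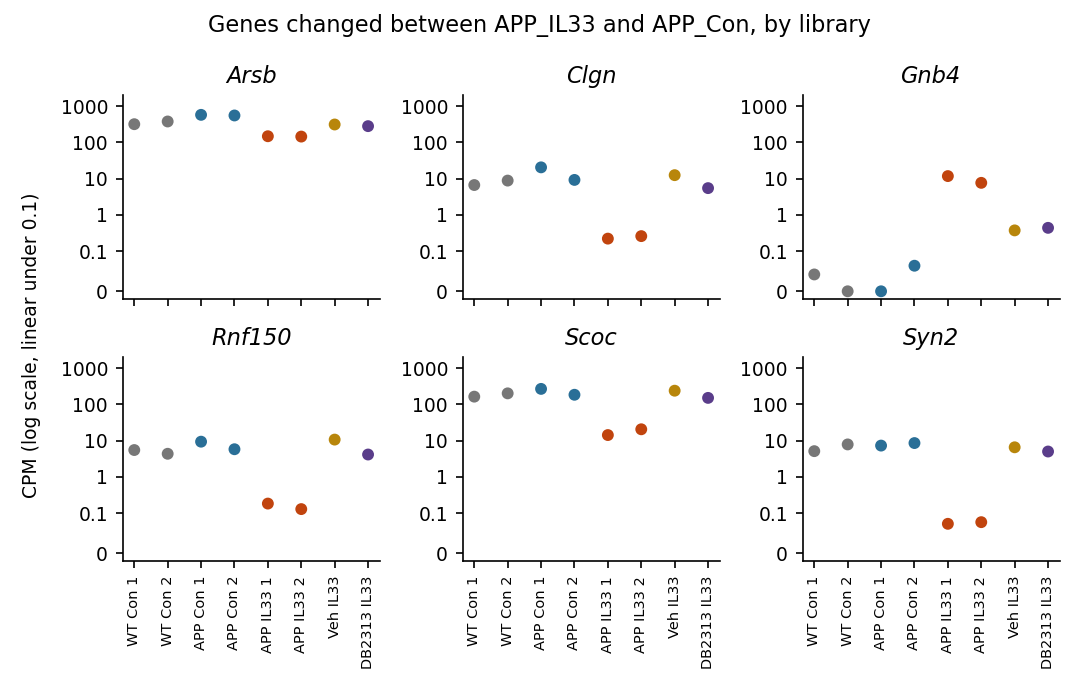
CPM of the 6 genes changed between APP_IL33 and APP_Con in microglia-like cells of each of the 8 libraries (y axis, log scale that is linear under 0.1 CPM; 1 point per library). The 2 APP_IL33 libraries stand apart, with Scoc at 14.3 and 20.7 CPM against 269.8 and 186 in APP_Con.

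The 6 genes were past an adjusted p of 0.05 of 12355 tested, with 288 at an unadjusted p under 0.05 in edgeR. The 288 are fewer than that limit would give by chance over 12355 unchanged genes, so they show no excess of small p-values. DESeq2 called 40, 16 higher and 24 lower, and the fit without a low-count filter called 23. The count fell to 0 without either APP_IL33 library, to 1 without either WT_Con library or in a fit of these 4 libraries only, and to 2 over all cells. Other genes always named gave Spi1 -0.10 ± 0.18, Il1rl1, the IL-33 receptor, 0.34 ± 0.32, Il1rap 0.18 ± 0.30, P2ry12 -0.16 ± 0.14, Tmem119 -0.06 ± 0.17, Trem2 -0.03 ± 0.20 and Cx3cr1 -0.05 ± 0.15.

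Of 32 lists, 6 passed camera with the preset correlation, and 0 passed with an estimated correlation or with fry. The MHC class II list stood higher, with 0 of 10 members past the test (0 adjusted over the list alone), a median of 1.54 and adjusted p = 2.93e-13, against adjusted p = 0.750 with an estimated correlation. Cholesterol and lipid handling stood lower, with a median of -0.27 over 22 genes (adjusted p = 0.000385; adjusted p = 0.750 with an estimated correlation). Disease-associated microglia genes stood lower, with a median of -0.12 over 26 genes (adjusted p = 0.0172; adjusted p = 0.750 with an estimated correlation). Cell cycle genes had a median of -0.24 over 27 genes (adjusted p = 0.0431; adjusted p = 0.770 with an estimated correlation). Oligodendrocyte markers had a median of -0.46 (adjusted p = 0.0301) and neutrophil markers one of -1.96 (adjusted p = 0.0172), both with adjusted p = 0.750 with an estimated correlation. Neutrophil-like cells made up 7.52% of APP_Con replicate 2, 0.420% of replicate 1, and 1.58% and 1.34% of APP_IL33. With the replicate number as a block, neutrophil markers did not pass camera with the preset correlation (adjusted p = 0.141). Other marker lists did not pass: border-associated macrophage (adjusted p = 0.305), monocyte (0.331), T or NK lymphocyte (0.331), dendritic cell (0.470), astrocyte (0.829), endothelial (0.257), mural (0.579), neuron (0.135) and choroid plexus (0.257). Lists of B lymphocytes, innate lymphoid cells, oligodendrocyte precursors, mast cells, erythroid cells and sex-linked genes had too few expressed members for a test. In the 5 lists that stood lower, 0 members passed singly, and 0 when adjusted over the list alone. Without APP_Con replicate 2, the disease-associated and lipid lists had adjusted p = 0.217 and 0.178, oligodendrocyte markers 0.527, and cell cycle and neutrophil markers turned upward (0.832 and 0.178). Without APP_IL33 replicate 1 the adjusted p was 0.196 for the disease-associated list, 0.392 for the lipid list and 0.111 for oligodendrocyte markers, and cell cycle turned upward (0.674). Without APP_IL33 replicate 2 it was 0.205 for oligodendrocyte and 0.412 for neutrophil markers. The cell cycle list had 0.0832 and 0.0869 without WT_Con replicate 1 or 2, 0.0749 over all cells and 0.0979 with the highest doublet scores removed, and the disease-associated list 0.0676 over all cells. Lists past the test numbered 13 without APP_Con replicate 1 and 3 without APP_Con replicate 2.

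MHC-II-positive cells were a larger part of the microglia-like cells in both APP_IL33 libraries than in the APP_Con library of the same number, although the intervals of the lower APP_IL33 share and the higher APP_Con share overlapped. They made up 27.3% (95% Wilson interval 25.6 to 29.1) and 8.93% (7.95 to 10.0) of cells in APP_IL33, 8.26% (7.0 to 9.73) and 3.08% (2.47 to 3.84) in APP_Con, and 2.74% (2.09 to 3.59) and 3.03% (2.39 to 3.84) in WT_Con. Shares were 38.0% (35.8 to 40.3) in Veh_IL33 and 11.4% (9.30 to 13.9) in DB2313_IL33. The APP_IL33 mean of 18.1 ± 13.01% was 12.5 points above the APP_Con mean of 5.67 ± 3.67% (SD, n = 2 each; two-sided exact permutation p = 0.333, the smallest that 2 against 2 libraries allow). Without thinning, the means were 60.0% and 49.0%. The difference was 3.26 points without APP_IL33 replicate 1 and 21.7 without APP_IL33 replicate 2. Cells near the limit, with 1 or 2 UMIs, made up 19.2% to 36.1% of each library.

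Oligodendrocyte-like cells, which should lack these genes, were positive in 0 of 27 cases in APP_IL33, which allows a share of up to 11.1%, and in 1 of 81 over all libraries (1.23%; median 5915 UMIs). Neutrophil-like cells were positive in 38.1% of 42 cells and 16.3% of 43 cells in the APP_IL33 libraries, and in 9.67% of 362 cells over all libraries. They held the microglial gene C1qa at 5881 and 4309 CPM, against 7595 and 5192 in microglia-like cells, and a median of 16047 and 21331 UMIs, so they are no measure of the background.

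**Figure D3:**
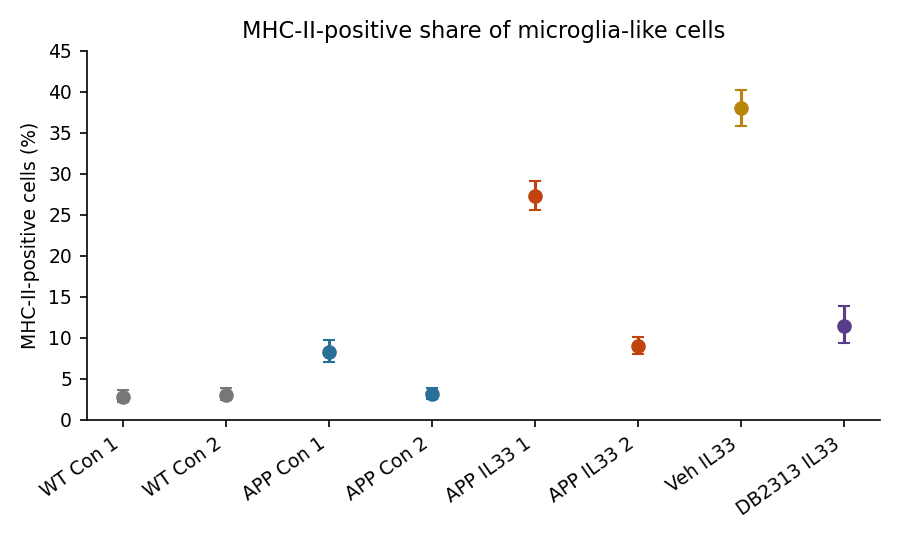
Share of microglia-like cells that were MHC-II-positive in each of the 8 libraries (y axis, percent; points, share; bars, 95% Wilson interval for counting error only). Shares run from 2.74% in WT_Con replicate 1 to 38.0% in Veh_IL33.

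APP_IL33 was also compared with WT_Con. In this comparison 403 genes changed, 330 higher and 73 lower, among them Baiap2l2 (8.13 ± 0.66), Igf1 (6.12 ± 0.64), Cst7 (5.95 ± 0.44), Apoe (3.62 ± 0.23), Lyzl4 (3.69 ± 0.62), the interferon-induced Ifi27l2a (3.54 ± 0.39) and Zbp1 (2.26 ± 0.40), and Scoc (-3.17 ± 0.30), Gp9 (-1.90 ± 0.17), Med21 (-1.25 ± 0.22) and Ccl2 (-1.17 ± 0.20), at edgeR adjusted p from 0.00294 to 0.0424. H2-Aa (3.75 ± 0.97, adjusted p = 0.0995), H2-Ab1 (3.12 ± 0.87, 0.117), Cd74 (2.17 ± 0.72, 0.170), P2ry12 (-0.62 ± 0.14, 0.0694) and Tmem119 (-0.76 ± 0.17, 0.0722) did not pass. In the MHC class II list 0 of 10 passed, and 3 rose when adjusted over the list alone. Of oxidative phosphorylation genes 18 of 34 rose (30 adjusted over the list alone). Of the genes called, 270 higher and 35 lower were also called between APP_Con and WT_Con, against 9.24 and 0.355 for independent lists of these sizes and a mean of 0.16 and 0.1 in simulated unchanged groups that share WT_Con; part of this may come from the shared WT_Con libraries. With 1 WT_Con library given to each comparison, a split chosen after the data were seen, 61 higher and 2 lower genes were called in both with WT_Con replicate 2 set against APP_IL33, and 78 and 2 the other way round, against 0.838 and 1.07 higher genes for independent lists. The count was 98 and 162 without WT_Con replicate 1 or 2, 237 and 234 without APP_Con replicate 1 or 2, and 134 and 68 without APP_IL33 replicate 1 or 2. DESeq2 called 1210 genes, the fit without a low-count filter 966, the fit over all cells 190 and a fit of these 4 libraries only 233. With the replicate number as a block 1461 passed, though no label says what that number marks.

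Positive and negative microglia-like cells of the same libraries (APP_IL33 replicates 1 and 2 and Veh_IL33) were compared for what marks MHC-II-positive cells. Positive cells were deeper in all 3 libraries, with a median of 10574.5 against 6462.5 UMIs, 9021 against 8870.5 and 6203 against 5129.5 in this order. In positive cells 23 of 26 disease-associated genes rose and 7 of 17 homeostatic genes fell (adjusted p = 0.164 and 0.169 for these lists with an estimated correlation), while border-associated macrophage markers rose in 3 of 11 genes and monocyte markers in 4 of 5. Spp1 stood at 711 ± 374 CPM in positive and 116 ± 80.3 CPM in negative cells (SD, n = 3 libraries; log2 fold change 2.69 ± 0.08, edgeR adjusted p = 1.84e-21). The chemokine gene Ccl8 rose by 2.70 ± 0.15, Gpnmb by 2.06 ± 0.10, and Cst7 from 1092 ± 447 to 2088 ± 620 CPM (0.99 ± 0.08). Tmem119, a microglial surface protein gene, fell from 995 ± 288 to 738 ± 135 CPM (-0.41 ± 0.07), and P2ry12, a purinergic receptor gene, from 1269 ± 355 to 970 ± 277 (-0.39 ± 0.06).

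In all, 532 of 10760 genes changed, 366 higher and 166 lower. Other rises of the largest 10 were in Tcap (1.72), Itgax (1.30), the heparanase gene Hpse (1.30), the amino acid oxidase gene Il4i1 (1.21), Lpl (1.13), Adssl1 (1.13) and the chemokine gene Ccl6 (1.05), with adjusted p of 3.35e-07 or less. Among the largest falls were Grap (-0.68), Camk2n1 (-0.66), Ecscr (-0.62), Crybb1 (-0.62), Tspan18 (-0.57), Lrba (-0.55), Cd27 (-0.54), Csad (-0.53) and Serpinf1 (-0.53), with adjusted p of 0.00594 or less. Apoe (0.61 ± 0.06) and Trem2 (0.24 ± 0.06, adjusted p = 0.0132) rose, while Spi1 (-0.16 ± 0.07, adjusted p = 0.185), Il1rl1 (0.17 ± 0.17), Il1rap (-0.53 ± 0.29) and Cx3cr1 (-0.03 ± 0.06) did not pass. The count was 330 without APP_IL33 replicate 1, 433 without replicate 2 and 470 without Veh_IL33. With class as the only term and no library block 0 genes passed, with DESeq2 154, and with the 1000-UMI cell rule 1036.

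Of the disease-associated list, 23 of 26 rose (26 adjusted over the list alone), including Axl (0.74 ± 0.08) and Tyrobp (0.33 ± 0.06); adjusted p = 0.164 with an estimated correlation. All 6 MHC class II genes outside the defining set rose (6 adjusted over the list alone), among them Ciita, the class II transactivator (3.21 ± 0.43), H2-DMa (1.00 ± 0.08) and H2-Oa (0.79 ± 0.11); adjusted p = 0.164 with an estimated correlation. In interferon response 11 of 24 rose (15 adjusted over the list alone; adjusted p = 0.169 with an estimated correlation), and in chemokines and cytokines 10 of 24 (11 adjusted over the list alone), such as Cxcl1 (0.94 ± 0.12) and the growth factor gene Csf1 (0.64 ± 0.08); adjusted p = 0.164 with an estimated correlation. Glycolysis rose in 9 of 15 genes (12 adjusted over the list alone, 1 lower), such as Pkm (0.43 ± 0.07) and Tpi1 (0.46 ± 0.08); adjusted p = 0.290 with an estimated correlation. Lipid handling rose in 10 of 21, such as Fabp5 (0.97 ± 0.07) (13 adjusted over the list alone, 1 lower; adjusted p = 0.164 with an estimated correlation) and oxidative phosphorylation in 7 of 34, such as Ndufa1 (0.48 ± 0.07) (23 adjusted over the list alone; adjusted p = 0.290 with an estimated correlation). MHC class I had 4 of 18 risen (8 adjusted over the list alone; adjusted p = 0.238 with an estimated correlation) and phagocytic receptors 6 of 22 (8 and 1 lower adjusted over the list alone; adjusted p = 0.164 with an estimated correlation). Lysosome genes had 6 risen and 2 fallen of 31 (13 and 3 adjusted over the list alone; adjusted p = 0.332 with an estimated correlation). Alternative activation had 3 of 8 risen (3 adjusted over the list alone), Retnla (5.26 ± 0.28), Mgl2 (2.39 ± 0.34) and the mannose receptor gene Mrc1 (1.15 ± 0.26); adjusted p = 0.252 with an estimated correlation. Retnla and Mrc1 rested largely on APP_IL33 replicate 2. Retnla stood at 62.4 CPM in its positive cells, against 1.83 in APP_IL33 replicate 1 and 2.17 in Veh_IL33. Without it Retnla had 3.11 ± 0.71 and Mrc1 0.67 ± 0.26 (adjusted p = 0.169).

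Homeostatic genes fell in 7 of 17 cases (11 adjusted over the list alone; adjusted p = 0.169 with an estimated correlation), and immediate early and dissociation genes in 6 of 25 (7 adjusted over the list alone), such as Klf2 (-0.35 ± 0.07) and Hspa1a (-0.37 ± 0.07); adjusted p = 0.164 with an estimated correlation. Ribosomal proteins and the mitochondrial genome passed upward with 0 members past the test, 0 adjusted over the list alone and adjusted p = 0.618 and 0.606 with an estimated correlation. Markers of other cells moved with these groups: border-associated macrophage markers rose in 3 of 11 genes (7 and 1 lower adjusted over the list alone), monocyte markers in 4 of 5 (4) and endothelial cell markers in 3 of 4 (3), each with adjusted p = 0.164 with an estimated correlation. Of 28 lists, 18 passed with the preset correlation and 0 with an estimated one. Among lists not past it, microglial transcription factors had 2 rises, Bhlhe40 (1.01 ± 0.11) and Hif1a (0.43 ± 0.08). Alzheimer risk genes had 3 rises, such as Ms4a6c (0.51 ± 0.11), and 1 fall, Bin1 (-0.25 ± 0.07). Complement had 1 rise, C3 (adjusted p = 0.00206 with edgeR and 0.378 with DESeq2). C3 stood at means of 5.10 and 1.66 CPM, and was lower in the positive cells of APP_IL33 replicate 2 (1.01 against 1.53 CPM). TGF-beta pathway had 1 fall, Smad7 (-0.32 ± 0.07), and IL-33 receptor and NF-kappaB and cell cycle 0 changes. Of markers of other cells, named after their values were seen, Cspg4 (2.26 ± 0.28) rose and the lymphocyte marker Il7r (-0.68 ± 0.14) fell. Il7r had adjusted p = 0.0604 over all cells and 0.204 with DESeq2.

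DB2313_IL33 and Veh_IL33 bear on what PU.1 inhibition does to microglia given IL-33. With 1 library each there is no replicate check, and the values describe these libraries. All 10 MHC class II genes stood lower in DB2313_IL33: Cd74 at 848 (95% exact Poisson interval 821 to 875) against 1863 CPM (1842 to 1884), H2-Aa at 172 (160 to 185) against 521 (510 to 532) and H2-Ab1 at 155 (144 to 167) against 335 (326 to 344). The list's median log2 ratio was -1.20 (counting interval -1.37 to -1.06), below all of 10000 matched random lists (percentile 0), which do not hold the spread that these genes share between libraries. As a ratio, H2-Aa lay further apart within APP_IL33 (901 and 145 CPM) and within APP_Con (171 and 51.6) than between these 2 libraries. H2-Eb1 did so within APP_IL33 (510 and 105) but not within APP_Con (90.8 and 31.4), against 384 and 108 in Veh_IL33 and DB2313_IL33. The share of MHC-II-positive cells was 11.4% against 38.0%. Interferon response genes stood higher, with a median of 0.60 and 22 of 24 members up (percentile 100), such as Bst2 (0.91). Spi1, which encodes PU.1, had a log2 ratio of 0.10 (360 against 337 CPM).

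Complement genes had a median of 0.46, with C1qb at 0.72, and the mitochondrial genome one of 0.60 with 13 of 13 members up. Immediate early and dissociation genes had a median of -0.36 (percentile 0). The disease-associated list had a median of 0.10 (percentile 99.2) and the homeostatic list one of 0.09 (percentile 96.7), with Apoe at 0.70, Cst7 0.37, Trem2 0.16, P2ry12 0.33, Tmem119 -0.17, Cx3cr1 -0.24, Il1rl1 0.22 and Il1rap -0.36. The 10 largest ratios up were Ttr (5.93; 4109 against 67.4 CPM), Enpp2 (4.71), Hpgd (3.32), F11r (2.62), Cd300lf (2.33), Fcrls (2.06), Gatm (2.04), Ifi44 (1.59), Pola2 (1.56) and Hdac1 (1.48). Those down were Cap1 (-2.37), Nrp1 (-2.10), Slamf8 (-1.87), H2-Eb1 (-1.83), Igsf8 (-1.72), Ptgfrn (-1.67), H2-Aa (-1.60), H2-DMa (-1.54), Slc1a3 (-1.47) and Hbegf (-1.44). For 12 of these 20 genes, Ttr and Enpp2 not among them, the 6 other libraries ranged more widely than these 2 differed. In barcodes with too few UMIs for a cell, which hold free RNA, Ttr stood at 60713 CPM in DB2313_IL33 and 412 in Veh_IL33. Ttr was also found in 100% of the DB2313_IL33 cells of each named class. Free RNA may thus have raised the Ttr ratio, which cannot be assigned to microglia. Whether this holds for Enpp2, the choroid plexus list and the astrocyte markers was not tested. Clu and Mt3 of the astrocyte markers were among the 10 leading genes of an unnamed cluster led by Ttr. That cluster had 111 of its 120 cells in DB2313_IL33, so the astrocyte markers are not a signal apart from the choroid plexus one. Choroid plexus genes (median 4.71), astrocyte (1.37) and neutrophil markers (1.06) stood higher in DB2313_IL33, and border-associated macrophage (-0.65), monocyte (-0.66) and dendritic cell markers (-0.77) lower. The single gene raised in APP_IL33, Gnb4, had a log2 ratio of 0.60 from 2 and 6 UMIs, with a counting interval of -1.50 to 2.40. The 5 genes lower in APP_IL33 had a median of -0.66 (percentile 0.145), and Rnf150, Clgn and Scoc among them are neighbours on chromosome 8. Every percentile in this comparison carries the limit given for MHC class II. Random lists do not hold the spread that members of a list share between libraries, so an extreme percentile alone does not point to the inhibitor.

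**Figure D4:**
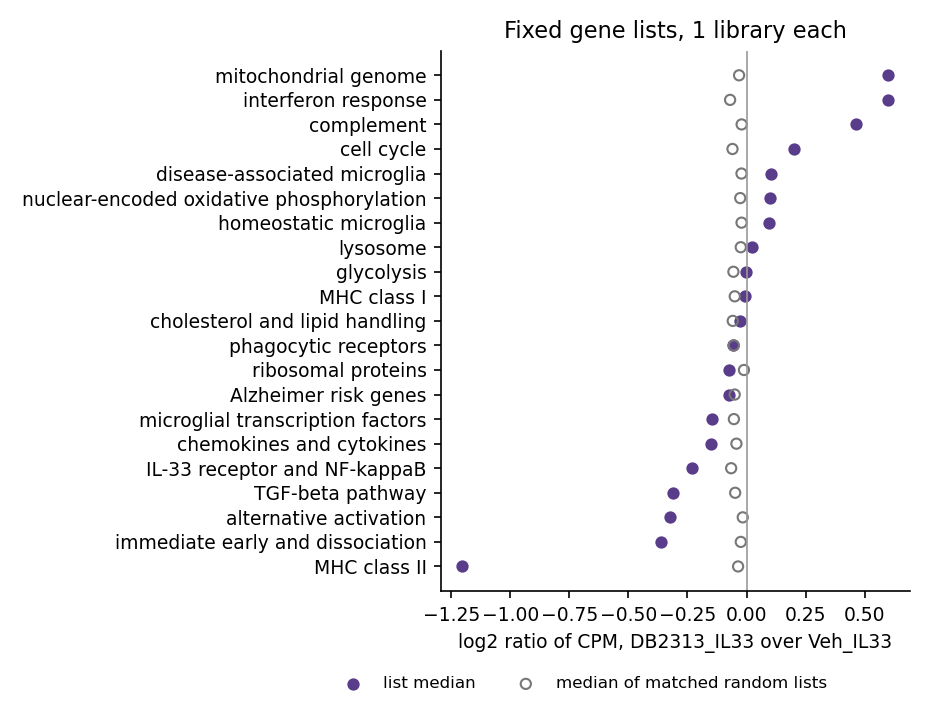
Median log2 ratio of CPM, DB2313_IL33 over Veh_IL33, for each fixed gene list, marker lists of other cells and sex-linked genes left out (x axis; filled points, list median; open points, median of 10000 random lists matched on expression; 1 library each, so no error bar can be given). MHC class II lies lowest at -1.20, and interferon response and the mitochondrial genome highest at 0.60.

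Across genes, the log2 fold changes of APP_IL33 against APP_Con and of APP_Con against WT_Con had a Pearson r of -0.295 over 12355 genes, which are not independent replicates. Both comparisons use the APP_Con libraries with opposite sign. Simulated unchanged groups gave a mean r of -0.501 (-0.551 to -0.449 in 50 simulations). The covariance was -0.101, against -0.0792 simulated (-0.0898 to -0.0665), a difference of -0.0220. For genes at 50 CPM or more, the covariance was -0.0310 against -0.0337 simulated, a difference of 0.00272, so its sign turned. With 1 APP_Con library given to each comparison, a split chosen after the data were seen, r was 0.0644 and the covariance 0.0343 with replicate 1 in the IL-33 comparison, and -0.0298 and -0.0152 the other way round. The r was -0.553 and -0.462 without APP_Con replicate 1 or 2.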

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

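Barcodes of 5 to 50 UMIs, too few for a cell, hold RNA that was free in the suspension. No comparison of groups used them, but the estimate of free MHC class II RNA below did. In DB2313_IL33 they held Ttr, the transthyretin gene made by choroid plexus epithelium, at 60713 CPM. The highest level in any other library was 1453 CPM, in APP_Con replicate 1. The cells of DB2313_IL33 held Ttr in every class, at 4109 CPM in microglia-like, 3818 CPM in border-associated macrophage-like and 3925 CPM in neutrophil-like cells. An unnamed cluster led by Ttr and Enpp2, both high in choroid plexus, had 111 of its 120 cells in this library.

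Gh, the growth hormone gene, stood at 245 CPM in the same kind of barcodes of APP_IL33 replicate 2 and at 0 in the other 7 libraries. Prl, the prolactin gene, stood there at 68.6 CPM, also against 0 elsewhere. Both are hormones of the anterior pituitary. No explanation was tested for either signal.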

How the results depend on the processing

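Removing cells by doublet score or over 25000 UMIs, and the replicate block with a 1000-UMI minimum, were chosen after seeing the data. Of the counts and values that answer a comparison, 87 of 114 held under the alternatives and 27 moved. With 1 library left out, 21 of 43 held and 22 moved. In either, 0 turned direction, which a count of genes or lists cannot do. A count held when it stayed within a fixed factor of the main one. The difference in MHC-II-positive share held at any value above 0. Medians for DB2313_IL33 held within their counting interval, which for Gnb4 ran from -1.50 to 2.40. The correlation held when its shift stayed within the spread of the simulations. Named genes past the test kept it in 751 of 950 refits for APP_Con against WT_Con, 69 of 114 for APP_IL33 against APP_Con, 183 of 209 for APP_IL33 against WT_Con and 639 of 717 for positive against negative cells, and 1 changed sign; genes short of it passed in 23 refits. For DB2313_IL33, 241 of 297 ratios of named genes stayed within their counting interval, 52 left it with their sign kept and 4 changed sign. Lists past the test kept it in 199 of 228 refits and in 98 of 114 with 1 library left out. The cause was not tested for any shift below, except where fewer samples or genes entered by construction.

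For APP_IL33 against APP_Con, 23 genes passed without a low-count filter, 2 over all cells, 40 with DESeq2 (16 higher, 24 lower) and 1 with only the 4 libraries compared. For APP_Con against WT_Con the counts were 813, 188, 1150 and 195 in that order, and for APP_IL33 against WT_Con 966, 190, 1210 and 233. Between positive and negative cells 0 genes passed with class as the only term, 1036 with a minimum of 1000 UMIs and 154 with DESeq2. With an estimated correlation 0 lists passed in both comparisons, and over all cells 21 lists passed for APP_Con against WT_Con. The MHC class II median for DB2313_IL33 was -1.49 with the 1000-UMI minimum and -1.38 over all cells. The correlation was -0.459 without a filter, -0.353 over all cells and -0.181 at 50 CPM or more.

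With 1 library left out, genes changed ran from 0 to 4 for APP_IL33 against APP_Con, 103 to 186 for APP_Con against WT_Con, 68 to 237 for APP_IL33 against WT_Con and 330 to 470 for positive against negative cells. Lists for APP_IL33 against APP_Con ran from 3 to 13 and the correlation from -0.553 to -0.257. Where leaving out 1 library leaves a group with 1, that library is assumed to vary like the others. The difference in MHC-II-positive share ran from 3.26 to 21.7 points, and from 8.28 to 15.0 under the other alternatives. The APP_IL33 mean was higher throughout, but the lower APP_IL33 library stood below the higher APP_Con library under some alternatives. These were 5 or more UMIs (4.05% against 4.45%), the 1000-UMI minimum (7.41% against 7.60%) and no thinning (54.1% against 58.4%). In each of them the exact permutation p was 0.667.

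Tested genes that changed sign lay short of the test, except Dab2 for APP_Con against WT_Con over all cells (-0.22). Under leaving out 1 library, log2 changes for APP_IL33 against APP_Con ran from -0.0502 to 2.10 for Cd74, -0.76 to 0.0196 for Cst7, -0.0915 to 0.0022 for Cx3cr1, -1.34 to 0.0489 for Fabp5, -0.18 to 0.72 for Il1rl1, -0.30 to 0.0762 for Spi1, -0.24 to 0.12 for Tmem119 and -0.14 to 0.083 for Trem2. For APP_Con against WT_Con they ran from -0.19 to 0.0721 for Cx3cr1, -0.28 to 1.67 for H2-Ab1 and -0.32 to 0.41 for Il1rap, and between positive and negative cells from -0.11 to 0.0361 for Cx3cr1. The adjusted p of the cell cycle list for APP_IL33 against APP_Con ran from 3.22e-07 to 0.832 and of neutrophil markers from 6.42e-30 to 0.412, with direction turned in 2 and 1 of these refits. Over all cells, H2-Aa (-0.55), H2-Ab1 (-0.81) and Cd74 (-0.31) turned lower in APP_Con than in WT_Con. Trem2 turned to 0.000765 for APP_IL33 against APP_Con, and Trem2 (-0.18), Spi1 (-0.22) and P2ry12 (-0.0139) turned lower in DB2313_IL33. Il1rap for APP_Con against WT_Con turned to -0.026 with upper-quartile scaling, -0.00552 without a filter and -0.00683 at the 5% mitochondrial limit. With the 1000-UMI minimum, Tmem119 for DB2313_IL33 turned to 0.0642 and Cx3cr1 in positive cells to 0.0168, and with positive cells from 2 UMIs Cx3cr1 turned to 0.00341.

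Removing the highest doublet scores turned Il1rap to -0.014, and removing cells over 25000 UMIs turned Il1rap to -0.0938 and Cx3cr1 for APP_IL33 against APP_Con to 0.000755. With the replicate number as a block, 4 genes passed for APP_IL33 against APP_Con, 1253 for APP_Con against WT_Con and 1461 for APP_IL33 against WT_Con. The block with the 1000-UMI minimum gave 1278 and 1457 for the last 2. Libraries of the same number deviated together with r = 0.197 for WT_Con and APP_Con, 0.102 for WT_Con and APP_IL33 and 0.504 for APP_Con and APP_IL33, but 2 numbers are too few to show that a number pairs the libraries, and the labels do not say what it marks. Under the block, neutrophil markers for APP_IL33 against APP_Con (adjusted p = 0.141) and endothelial markers for APP_Con against WT_Con (adjusted p = 0.115) no longer passed.

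Depth limits DB2313_IL33 most, with 4571301 UMIs over its microglia-like cells. The log2 ratio of Gnb4, the gene raised in APP_IL33, rests on 2 and 6 UMIs there and ran from 0.13 to 1.37 under the alternatives. All kept cells gave no value for it, since 0 raised genes passed.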

Other observations

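The tests of explanations given here were all chosen only after the result was seen. Border-associated macrophage-like cells, led by Pf4, Mrc1 and F13a1, made up 4.50% and 15.1% of cells in WT_Con, 2.88% and 4.53% in APP_Con, 3.79% and 4.72% in APP_IL33, 0.513% in Veh_IL33 and 0.957% in DB2313_IL33. The lowest UMI total of a cell differed between libraries, which can set these shares. Microglial markers were detected in 95.9% of these cells on average. Their median depth was 16325 UMIs, and a cell's depth was at the median 1.74 times that of its library. They may thus be doublets or mixed droplets in part, so these shares need not be those of macrophages alone. In APP_IL33 they were MHC-II-positive in 57.4% and 36.4% of cells at 1000 UMIs, in APP_Con in 52.1% and 39.0% and in WT_Con in 44.6% and 49.8%. Part of these cells are known to carry MHC class II at rest. An unnamed cluster of 517 cells was led by Plac8, Cd209a, Ccl17 and Mgl2, and 129 of its cells came from Veh_IL33.

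Replicates of one group differed in named genes that were chosen after their values were seen. A microglia-like cluster led by Tnfaip2, Il12b, Cxcl1 and Ptgs2, genes of the inflammatory response, held 570 and 776 cells of replicate 1 of APP_Con and APP_IL33, against 46 and 57 of replicate 2. F11r, which encodes a junctional adhesion molecule, stood at 151 and 18.9 CPM in the APP_Con libraries, while Igsf8 stood at 65.0 and 165 CPM and Slamf8 at 12.7 and 54.3 CPM. On GRCm38 these 3 genes start at 171437561, 172312367 and 172581377 on chromosome 1. Veh_IL33 and DB2313_IL33 differed in the same direction as APP_Con replicate 2 and replicate 1, with F11r at 34.5 and 212 CPM, Igsf8 at 212 and 63.9 CPM and Slamf8 at 68.1 and 18.4 CPM.

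The genes changed between APP_IL33 and APP_Con may follow inherited chromosome segments. Rnf150, Clgn and Scoc lie side by side on chromosome 8, which raised the idea, but among the other 16 genes with an unadjusted p under 0.001, 1 pair lay within 1 Mb, against a mean of 0.221 in random draws (permutation p = 0.1996). An effect of IL-33 on these genes in every library that received it was argued against, since 11 of the 12 values in Veh_IL33 and DB2313_IL33 lay nearer to APP_Con on a log2 scale and 9 in CPM, the exceptions being Arsb in DB2313_IL33 (282 CPM) on both scales and, in CPM, Arsb in Veh_IL33 (313) and Clgn in DB2313_IL33 (5.47). For Gnb4, Syn2 and Arsb, inherited segments and an effect of IL-33 in the APP_IL33 animals cannot be told apart, since 0 of these 3 genes had another such gene within 1 Mb and a segment may hold 1 measured gene that differs. For the chromosome 8 genes the 2 cannot be told apart either, since a single segment would leave no other neighbouring pairs.

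Veh_IL33 and DB2313_IL33, labelled WT, resembled APP_Con, with 91.7% and 90.7% of 397 genes nearer to APP_Con than to WT_Con. Transgenic animals under a WT label may account for this, since the median position of Veh_IL33 was 1.07 and that of DB2313_IL33 was 1.08, where 0 is WT_Con and 1 is APP_Con. An effect of IL-33 on the same genes in WT animals cannot be told apart from it, because no other library comes from WT animals given IL-33. The APP_IL33 libraries, at 0.891 and 0.900, speak of APP/PS1 animals only. Sex differed between these 2 libraries and the other 6, and its part was not tested.

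MHC-II-positive microglia-like cells were more frequent in the libraries given IL-33 than in the WT_Con libraries, and the lowest of these shares, 8.93%, lay close to the highest of APP_Con, 8.26%. An inherited segment at the MHC locus marked by low Msh5, a gene of the locus, was argued against as the whole cause. Msh5 was low in APP_IL33 (2.24 and 2.02 CPM against 30.0 and 43.8 in APP_Con). Yet Veh_IL33 and DB2313_IL33, 1 library each, held it at 56.0 and 54.9 CPM with shares of 38.0% and 11.4%. WT_Con replicate 2 held Msh5 low as well, at 2.88 CPM (30.1 in replicate 1), with a share of only 3.03%. H2-Q6, a gene of the locus with near-identical paralogs, grouped the libraries otherwise. It stood at 21.3 and 53.9 CPM in WT_Con, 31.9 and 0.794 in APP_Con, 46.1 and 33.4 in APP_IL33, 1.49 in Veh_IL33 and 1.31 in DB2313_IL33. Other segments of the locus therefore stay open. Free RNA was argued against too, since it gave at most 14.2% of the MHC class II level in Veh_IL33, 8.45% in DB2313_IL33 and 2.57% and 4.21% in APP_IL33. Whether border-associated macrophages or their doublets were a source was not settled. Of the 366 genes risen in positive cells, 278 were lower in border-associated macrophage-like cells than in positive cells. Mixing with such cells at their mean level would not bring these 278 to the level in positive cells. The macrophage-like cells may themselves be mixed with microglia, since microglial markers were detected in 95.9% of them on average. However, the genes were picked for being high in positive cells, which favours this result, and 297 were lower in neutrophil-like cells too. In the unnamed cluster led by Plac8 220 were lower (60.1%), and its part in the others, such as Ccl8 (109 CPM there, 55.5 in positive cells), stays open. IL-33 may raise the share, as a hypothesis left open by APP_IL33 against APP_Con (two-sided exact permutation p = 0.333, the smallest that 2 against 2 libraries allow), the sex of the mice and the doubtful genotype labels.

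For the 532 genes changed between positive and negative sums, the 10 splits of the 6 sums are too few for a share under 0.05. Only 1 of the 10 splits, the real one, gave as many genes, and the highest of the others gave 124. The splits with 124 parted the positive and negative sums of only 1 library, so they are no like reference under the library block. The other splits that parted the sums of all 3 libraries gave 0, and they are fewer still than the 10.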
